A study of Mus musculus with 18 samples.

How the data were processed

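Poly-A RNA of CD8+ T cells from mouse spleen and lymph node was sequenced in 18 libraries, 3 from each of 6 groups, per the labels. The groups cross 3 CRISPR/Cas9 targets (Rosa26, a neutral site that serves as the control, Atf4 and Cebpg) with culture for 24 hours with or without halofuginone, an inhibitor of prolyl-tRNA synthetase. Per the labels' protocols, RNA was isolated with a Zymo kit and DNase I, messenger RNA was captured on poly-oligo beads, and a directional library was made with random hexamers and dUTP. Per the submitters' processing notes, reads passed through FastQC, MultiQC, Trimmomatic, STAR and HTSeq against the mouse build GRCm39, and edgeR was used. The versions and settings of these tools, the strand setting of the counting, the annotation release and the length of the reads are not given in the sources used here. The deposited table holds raw read counts per gene, per the file headers, and the values were whole numbers.

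The deposited table held 14695 genes, already filtered, a point tested on the values. The lowest third-highest level of any gene was 0.597 CPM (counts scaled to a library of 1 M, mega, counts), which is 10.1 counts in a library of median depth, and filterByExpr with a minimum count of 10 kept all 14695 genes. Slc7a11, a gene of the panel, was not analysed here. Names were blank for 449 genes; 431 of these were filled from a GRCm38 gene annotation by identifier, 18 kept the identifier, and 4 duplicated names were labelled with it. The same annotation gave a gene type for 14335 genes, and annotated positions gave gene lengths and the order of neighbouring genes. Total counts ran from 14.2 to 20.3 M per library. Without the strand setting, values of genes that overlap on opposite strands are uncertain. Near-identical copies, such as histone genes, Gbp10 and Gbp11, and ribosomal proteins with their pseudogenes, are uncertain because reads may be shared among them.

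All 18 libraries entered 1 fit with a term for each of the 6 groups: edgeR 4.0.16 in R 4.3.3, TMM scaling factors, and quasi-likelihood F tests with robust prior. Fold changes kept the default prior count of the fit, so those of genes near 0 counts are little shrunken. A prior count of 2 was used only where levels were taken as log2 CPM. The 11 comparisons were halofuginone in each of the 3 genotypes, each knockout against Rosa26 without and with halofuginone, the knockouts against each other with halofuginone, and 3 interactions. A gene counted as risen or fallen at an adjusted p under 0.05 (Benjamini-Hochberg over all genes of the comparison). A fold change is log2 throughout and ± beside it is the standard error from the fit; beside a level in CPM, ± is the SD over the 3 libraries. Intervals and floors cover counting error only, and a floor is 3 counts per library.

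A total of 27 gene lists were fixed before the data were examined. They held 568 members, of which 511 were measured. The 21 lists of biology were integrated stress response targets, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, mitochondrial aminoacyl-tRNA synthetases, serine and one-carbon metabolism, asparagine, proline and glutamate metabolism, glutathione and transsulfuration, nucleotide synthesis, ER chaperones, ribosomal proteins, cholesterol synthesis, glycolysis, oxidative phosphorylation, cell cycle, effector CD8 genes, naive and memory CD8 genes, checkpoint and exhaustion genes, p53 targets, interferon response, autophagy and lysosome, and mitochondrially encoded mRNAs. The others were markers of CD8 T cells, CD4 T cells, B cells, myeloid cells, NK cells, and erythroid cells and platelets. Each list was tested against all other genes with camera (limma 3.58.1, correlation set to 0.01), adjusted over the 27 lists, and members were also adjusted over the list alone.

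Genes were named by a fixed rule. It takes the targeted genes Atf4 and Cebpg, and a panel (Asns, Chac1, Trib3, Ddit3, Psat1, Phgdh, Mthfd2, Slc7a11, Gzmb, Ifng, Tcf7, Mki67). It adds the 6 highest and 6 lowest fold changes past the threshold with at least 5 CPM in a compared group, levels that do not overlap between the groups where 2 groups are compared, and no predicted gene name. It further adds the 3 members with the smallest p of the 5 lists of biology with the smallest camera p, and 1 member of each other list described. A gene named in 1 comparison may be given in another, and genes outside the rule are said to be so where they appear. Some genes that the rule names, 1 of the panel among them, are not reported here.

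The share of the halofuginone response that a knockout kept was the median log2 fold change in the knockout divided by the median in Rosa26, over genes that changed by at least 2-fold in Rosa26. The overlap of calls between the knockouts was set beside 10 simulations with no shared change but the same controls. Every way to split the 6 libraries of a 2-group comparison into 3 against 3 was tested, and 30 of the 200 regroupings for each interaction. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, a filter of 5 CPM in 3 libraries, a replicate block on the labels' replicate number, a fit of only the compared groups, a prior that is not robust, each library left out in turn, camera with an estimated correlation, and fry. A filter that only asks for a total above 0 adds no gene here. After the data were seen, 2 more were added: leaving out 3 libraries low in counts of unconfirmed transcripts, and the share of those counts as a covariate.

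The fit was tested on simulated data in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. For halofuginone in Rosa26 (14351 genes), 52.2%, 73.1% and 81.8% of the changed genes were recovered at those sizes, with 5 false calls of 143. For untreated Cebpg knockout (14350) the shares were 49.3%, 71.6% and 86.4%, with 4 false calls of 142. For the interaction with Cebpg knockout (14338) they were 41.8%, 58.2% and 68.2%, with 7 of 119. For the interaction between the knockouts (14311) they were 37.3%, 53.7% and 69.7%, with 5 of 112. These rates hold for such data only: halofuginone in Rosa26 had 7008 calls, and the real spread differed by treatment. No column of the table was left out.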

Results

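Poly-A RNA was sequenced in 18 libraries of mouse CD8+ T cells, 3 in each of 6 groups. In order of replicate number, Rosa26 libraries held 17.5, 17.8 and 18.8 M (mega) counts without and 20.3, 17.7 and 15.7 M with halofuginone. Atf4 knockout libraries held 16.1, 17.0 and 14.9 M without and 15.2, 14.7 and 18.01 M with it. Cebpg knockout libraries held 17.9, 17.5 and 15.1 M without and 16.7, 14.2 and 14.2 M with it. The labels do not say whether libraries of a group came from separate mice or cultures, so the p-values measure only the spread between these samples.

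The mRNA of both targeted genes was present in every group. Atf4, a transcription factor of the integrated stress response, stood at 268 ± 12.5 CPM in untreated Rosa26 cells and at 379 ± 42.8 CPM with halofuginone. In Atf4 knockout cells it was 285 ± 14.4 and 315 ± 57.3 CPM, and in Cebpg knockout cells 278 ± 6.57 and 316 ± 26.6 CPM. Cebpg, a transcription factor that pairs with ATF4, went from 53.7 ± 1.28 to 173 ± 8.67 CPM in Rosa26, from 58.9 ± 0.89 to 131 ± 7.29 CPM in Atf4 knockout and from 56.4 ± 2.33 to 101 ± 6.37 CPM in Cebpg knockout cells. Atf4 mRNA in its own knockout did not differ from Rosa26 past the threshold, at 0.09 (adjusted p = 0.549) without and -0.26 (adjusted p = 0.0587) with halofuginone. Cebpg mRNA in its own knockout was 0.07 (adjusted p = 0.498) without and fell by 0.78 (adjusted p = 3.2e-08) with the drug. Small insertions or deletions need not lower the count of a gene, so these values do not check the genotype labels.

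Counts in 829 genes of unconfirmed transcripts (the annotation's class TEC, for transcripts that await experiments) set some libraries apart. They took 0.09997% to 0.133% of the counts in untreated Rosa26 libraries and 0.194% to 0.2498% in untreated libraries of both knockouts. With halofuginone, Rosa26 replicate 2 held 0.0542% against 0.189% to 0.225% in the other libraries of its group. Atf4 knockout replicate 3 held 0.0735% against 0.216% to 0.302%, and Cebpg knockout replicate 3 held 0.151% against 0.264% to 0.287%. The nuclear transcript Malat1 moved with them: 672 CPM in that Rosa26 library against 2074 to 2607, 1158 against 2404 to 3415 in the Atf4 knockout, and 1960 against 3237 to 3580 in the Cebpg knockout. The first principal component of the variance within groups carried 45.8%, and on it these 3 libraries stood lowest of their groups. No 2 libraries of a group were duplicates. The chi-square per degree of freedom between them was 2.01 to 6.65 in untreated and 6.28 to 41.5 in halofuginone groups. The fit gave each gene 1 estimate of spread for all 18 libraries. The p-values may therefore be too large for untreated and too small for treated comparisons.

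**Figure D1:**
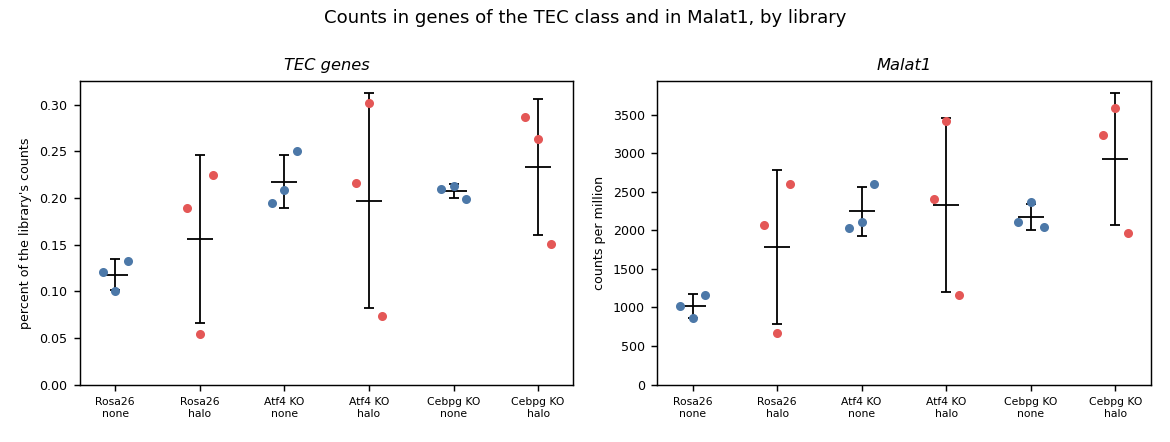
Share of counts in genes of unconfirmed transcripts (percent, left) and Malat1 (CPM, right) by group, where each point is 1 of the 18 libraries, horizontal lines are means and error bars are the SD. The lowest halofuginone library of each genotype sat at 0.0542% (Rosa26), 0.0735% (Atf4 knockout) and 0.151% (Cebpg knockout).

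Markers of CD8 T cells were high in every library, and most of those of other blood cells were low. Cd8a, a chain of the CD8 coreceptor, ran from 930 to 1170 CPM and Thy1 from 800 to 1470 CPM. Foxp3, the regulatory T cell factor, ran from 4.73 to 11.3 CPM, and Zbtb7b, which encodes the CD4 lineage factor ThPOK, from 1.85 to 29 CPM. Apart from Ighm the B cell genes reached at most 7.2 CPM (Cd79b and Ighd), with Cd79a at most 0.793 CPM and H2-Ab1 at most 6.27 CPM. The myeloid genes reached at most 6.87 CPM (Cd68), and the erythroid and platelet genes at most 12.2 CPM (Itga2b). Ighm, at 380 to 481 CPM, Nkg7, at 189 to 318 CPM, and the CD4 list members Il2ra, at 514 to 820 CPM, and Ikzf2, at 16.2 to 99.9 CPM, can also be transcribed in CD8 T cells. Of the marker lists, 10 of 10 CD8 T, 4 of 7 CD4 T, 7 of 12 B, 3 of 14 myeloid, 2 of 8 NK and 3 of 9 erythroid and platelet genes were measured.

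The first comparison asked what halofuginone did to control cells. In Rosa26 cells it raised most genes of the integrated stress response and of the naive and memory list, and it lowered genes of cell division, cholesterol synthesis and nucleotide synthesis. Asns, which makes asparagine, rose from 43.0 to 86.8 CPM (1.01 ± 0.0824), and Trib3, a pseudokinase, rose from 51.3 to 319 CPM (2.64 ± 0.113). Atf5, a transcription factor, rose from 10.4 to 100 CPM (3.28 ± 0.145). Ddit3, which encodes CHOP, rose from 6.61 to 44.7 CPM (2.76 ± 0.216), and Chac1, which degrades glutathione, from 3.43 to 8.18 CPM (1.25 ± 0.262). Gpt2, a mitochondrial alanine transaminase, rose by 2.29, and the glycine transporter Slc6a9 by 3.63. Of 21 integrated stress response targets, 19 rose and 0 fell, and 2 were not past the threshold (median 1.04, adjusted p = 1.7e-11 by camera and adjusted p = 0.105 with an estimated correlation). Atf4 mRNA itself rose by 0.50 (adjusted p = 0.000470) and Cebpg by 1.69 (adjusted p = 6.6e-14).

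Genes of amino acid supply did not move as 1 group. Among 15 amino acid transporters 8 rose and 2 fell (adjusted p = 0.000603, and adjusted p = 0.126 with an estimated correlation). Among 20 cytosolic aminoacyl-tRNA synthetases 9 rose and 7 fell (adjusted p = 0.0239, and adjusted p = 0.679 with an estimated correlation); Aars1, the alanyl-tRNA synthetase, rose by 1.22. Adjusted over the list alone, 8 synthetases fell. Of the 17 mitochondrial synthetases 4 rose, among them Wars2 by 0.98, and 4 fell (adjusted p = 0.907). The serine synthesis genes Psat1 and Phgdh fell by 0.30 (adjusted p = 0.000844) and 0.33 (adjusted p = 0.0110), and Mthfd2, a mitochondrial folate enzyme, was 0.10 (adjusted p = 0.158). The call of Phgdh ended without Rosa26 halofuginone replicate 1 (adjusted p = 0.0506) or replicate 3 (adjusted p = 0.0569). In serine and one-carbon metabolism 2 of 14 rose and 6 fell (adjusted p = 0.106); Tyms, thymidylate synthase, fell by 1.23. In asparagine, proline and glutamate metabolism 4 of 15 rose and 7 fell, and the list had a median of -0.0955, a mean of 0.0782 and a test direction up (adjusted p = 0.986). In glutathione and transsulfuration 6 of 15 rose and 7 fell, Gsr by 0.53, with a median of -0.35, a mean of 0.0763 and a test direction down (adjusted p = 0.817).

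Cell cycle, cholesterol and nucleotide genes fell nearly as whole lists. Of 30 cell cycle genes 29 fell and 1 rose (median -1.5, adjusted p = 8.0e-51), with Mki67, the proliferation marker, at 1366 CPM untreated and 450 CPM with the drug (-1.60 ± 0.0718). Cenpa, the centromeric histone, fell by 1.90, as did the mitotic genes Kif11 (-1.503) and Bub1b (-1.74). Of 24 genes of cholesterol synthesis 23 fell and 0 rose (median -1.09, adjusted p = 2.9e-26); Hmgcs1 fell by 1.57 and Insig1 by 1.67. All 20 genes of nucleotide synthesis fell (median -0.584, adjusted p = 1.2e-12, and adjusted p = 0.125 with an estimated correlation). The ribonucleotide reductase genes Rrm2 and Rrm1 fell by 1.34 and 1.29 and thymidine kinase, Tk1, by 1.17. Of 21 glycolysis genes 17 fell and 0 rose (adjusted p = 6.2e-10, and adjusted p = 0.125 with an estimated correlation). Among them the lactate exporter Slc16a3 fell by 1.89, Pfkl by 1.01 and Pgam1 by 1.09. Of 42 genes of oxidative phosphorylation 27 fell, Ndufs1 by 0.50, and 0 rose (adjusted p = 0.000879, and adjusted p = 0.730 with an estimated correlation). ER chaperones fell in 13 of 21 cases and rose in 2, with Sdf2l1 down by 1.32 (adjusted p = 0.000992, and adjusted p = 0.555 with an estimated correlation). Of 10 mitochondrially encoded mRNAs 3 fell, mt-Nd2 by 0.64 (adjusted p = 0.158). Of 79 ribosomal protein genes 17 rose, Rpl5 by 0.57, and 1 fell (adjusted p = 0.0573); adjusted over the list alone 8 rose and 0 fell.

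Genes of T cell state moved toward the naive and memory side while effector genes were mixed. Of 18 naive and memory CD8 genes 13 rose and 4 fell (median 0.707, adjusted p = 1.3e-06, and adjusted p = 0.105 with an estimated correlation). Bach2, a repressor of effector programmes, rose by 1.87, while Tcf7, the factor TCF1, was 0.08 (adjusted p = 0.472). Of 20 effector genes 7 rose, Fasl by 1.59, and 4 fell (adjusted p = 0.793). Gzmb, granzyme B, fell by 0.31 (adjusted p = 0.00283), Ifng was 0.56 ± 0.632 (adjusted p = 0.501) at under 1 CPM, and Zfp683, which encodes Hobit, fell by 2.34. Checkpoint and exhaustion genes rose in 8 of 15 cases, Ctla4 by 1.15, and fell in 5 (adjusted p = 0.158). Of 17 p53 targets 9 rose, Trp53inp1 by 1.03, and 2 fell (adjusted p = 0.000992, and adjusted p = 0.125 with an estimated correlation). Of 23 interferon response genes 14 rose, the nucleic acid sensor Zbp1 by 1.65, and 3 fell (adjusted p = 0.000562, and adjusted p = 0.396 with an estimated correlation). Of 25 autophagy and lysosome genes 9 rose, Atg12 by 0.90, and 2 fell (adjusted p = 0.101).

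Markers of blood cell types were tested as lists too. Of 4 CD4 T markers 3 rose, Zbtb7b from 3.92 to 26.8 CPM (2.77), and 0 fell (adjusted p = 0.000859, and adjusted p = 0.105 with an estimated correlation). Of 10 CD8 T markers 1 rose and 3 fell, Lck by 0.40, with a median of 0.03, a mean of -0.00747 and a test direction down (adjusted p = 0.983). Of 7 B cell markers 1 rose, Ighm by 0.18, and adjusted over the list alone 0 did; that call ended without any of 4 libraries (adjusted p from 0.0726 to 0.141), and the median was -0.0214, the mean 0.169 and the test direction up (adjusted p = 0.907). Mpeg1 rose by 2.72 among 3 myeloid markers, of which 2 rose, and both NK markers rose, Nkg7 by 0.43 (each list adjusted p = 0.352). Itga2b rose by 1.21 among 3 erythroid and platelet markers, of which 1 rose and 2 fell (adjusted p = 0.793).

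The highest fold changes in Rosa26 were those of Cox6a2, a muscle isoform of a cytochrome oxidase subunit (4.75, from 0.196 to 5.45 CPM), the guanylate-binding genes Gbp11 (4.67) and Gbp10 (3.60), Myof (3.78), Kcnip2 (3.75) and Slc6a9. The lowest were those of the desaturase genes Scd1 (-3.03) and Fads2 (-2.59), the histone genes H2ac8 (-2.87), H3c10 (-2.38) and H2bc12 (-2.35), and Zfp683. The Gbp and histone values are uncertain because near-identical copies may share reads. By edgeR, 7008 of 14695 genes changed in Rosa26, 3461 higher and 3547 lower; 1020 were higher and 571 lower by at least 2-fold. The share of higher genes was 49.4%, and upper-quartile scaling, with 4083 higher and 3166 lower, made it 56.3%.

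**Figure D2:**
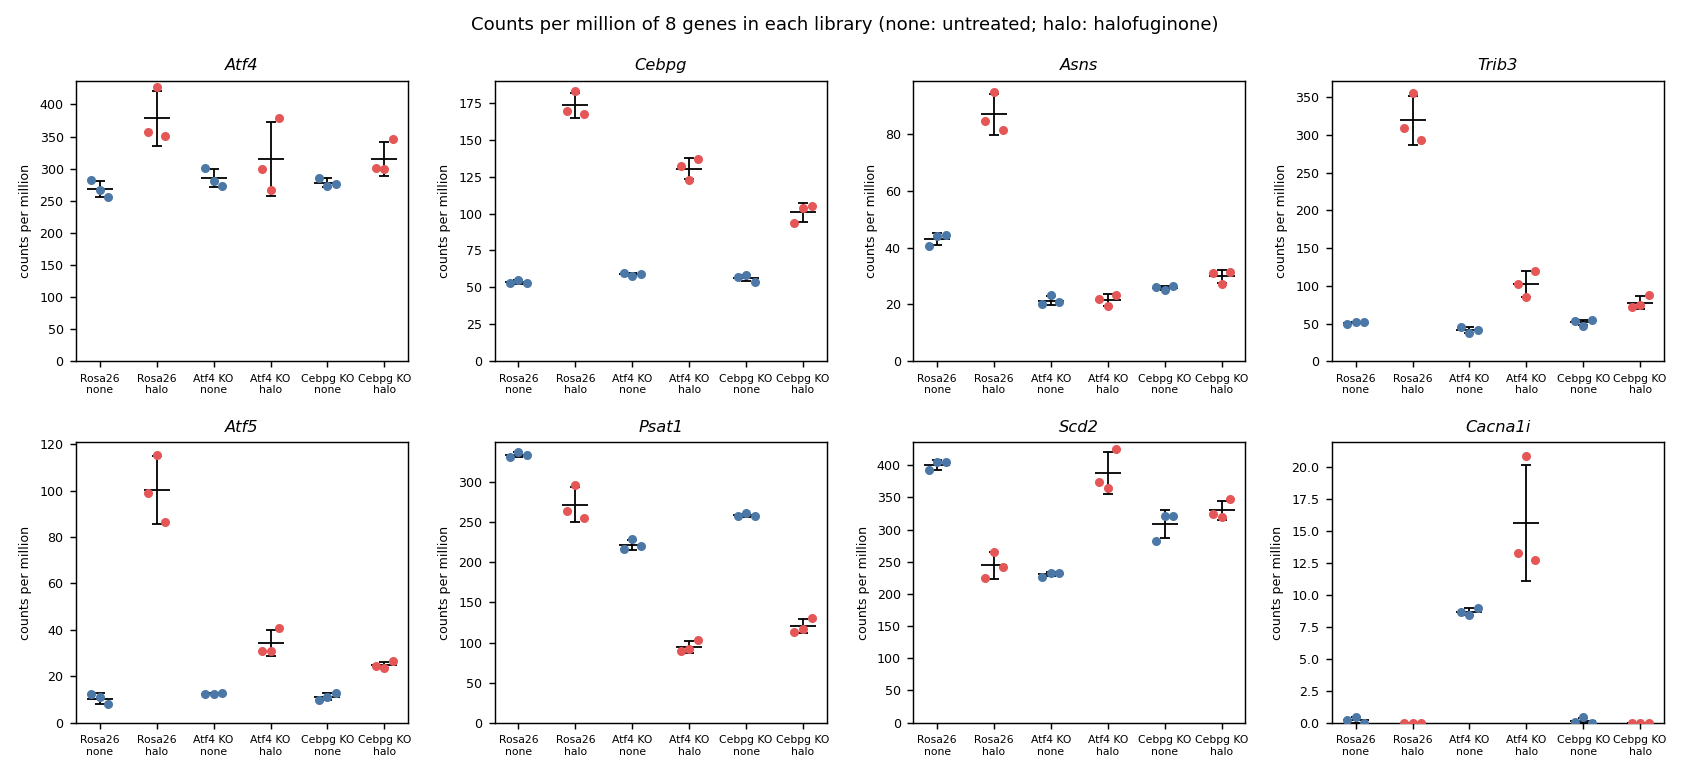
Levels of 8 genes (CPM) in the 6 groups, where each point is 1 library, horizontal lines are means and error bars are the SD (n = 3). Asns stood at 86.8 CPM in Rosa26 with halofuginone and at 21.5 and 29.9 CPM in the Atf4 and Cebpg knockouts with it, and Cacna1i was above 8 CPM in the Atf4 knockout alone.

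The same drug was then compared within Atf4 knockout cells. There fewer stress response targets passed the threshold, while cell division and cholesterol synthesis genes still fell. Asns was 0.01 (adjusted p = 0.928) and Chac1 was -0.04 (adjusted p = 0.933), so neither passed the threshold. Trib3 rose by 1.31 ± 0.113, Ddit3 by 1.67 ± 0.205, Bbc3, a BH3-only cell death gene, by 1.44 and Cebpg by 1.15. Psat1 fell by 1.23 ± 0.0679, Phgdh by 0.59 and Mthfd2 by 0.67 (adjusted p = 6.6e-09). Among 21 integrated stress response targets 11 rose and 1 fell (median 0.42, adjusted p = 0.00933, and adjusted p = 0.523 with an estimated correlation), and 12 rose when adjusted over the list alone. Of 14 serine and one-carbon genes 11 fell and 1 rose, with Tyms down by 1.60 (adjusted p = 1.5e-05, and adjusted p = 0.236 with an estimated correlation). Of 20 cytosolic synthetases 12 fell and 4 rose, Aars1 by 0.73 (adjusted p = 0.204). Among 15 amino acid transporters 5 rose, Slc1a4 by 1.58, and 8 fell, with a median of -0.184, a mean of 0.251 and a test direction up (adjusted p = 0.668). Glutathione and transsulfuration fell in 8 of 15 genes, Txnrd1, a thioredoxin reductase, by 0.87 (adjusted p = 0.0321, and adjusted p = 0.523 with an estimated correlation).

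Division and cholesterol lists fell in Atf4 knockout cells as well. Among 30 cell cycle genes 29 fell and 1 rose (median -1.46, adjusted p = 2.0e-55), with Plk1, a mitotic kinase, down by 1.97, Bub1b by 2.00, Tpx2 by 1.99 and Mki67 by 1.70. Of 24 cholesterol genes 23 fell (median -0.965, adjusted p = 2.6e-16), with Hmgcs1 down by 1.25. Of 20 nucleotide genes 18 fell, Tk1 by 1.86, Rrm1 by 1.74 and Rrm2 by 1.68 (adjusted p = 3.2e-14, and adjusted p = 0.164 with an estimated correlation). Among 21 glycolysis genes 17 fell, Slc16a3 by 1.89, and 2 rose (adjusted p = 1.1e-07, and adjusted p = 0.236 with an estimated correlation). Among 18 naive and memory genes 14 rose and 3 fell, with S1pr1, the egress receptor, up by 2.30, Bach2 by 1.60, Lef1 by 0.99 and Tcf7 by 0.71 (adjusted p = 3.0e-06, and adjusted p = 0.125 with an estimated correlation). Gzmb fell by 0.44. The highest fold changes were those of Sdc4, a syndecan (4.99), Ssc5d (4.53), Acoxl (3.80), Abca1, a cholesterol exporter (3.61), Slfn5 (3.61) and Myof (3.36). Among the lowest were those of Fads2 (-2.96), the histone genes H2bc11 (-2.80) and H3c3 (-2.62), Fbln1 (-2.57) and Sapcd2 (-2.51). By edgeR 3397 genes were higher and 3897 lower, 7294 in total, of which 900 and 927 moved by at least 2-fold. Higher genes made up 46.6% of the calls, 50.8% with RLE and 52.0% with upper-quartile scaling.

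In Cebpg knockout cells halofuginone again left Asns (0.21, adjusted p = 0.0527) and Chac1 (0.35, adjusted p = 0.343) below the threshold. Trib3 rose by 0.60 ± 0.112, Ddit3 by 2.13 ± 0.215 and Bbc3 by 1.42, while Psat1 fell by 1.11, Phgdh by 0.71 and Mthfd2 by 0.64. Of 21 integrated stress response targets 10 rose and 2 fell (median 0.383, adjusted p = 0.0385, and adjusted p = 0.648 with an estimated correlation). Among 14 serine and one-carbon genes 11 fell and 3 rose, with Tyms down by 1.74 (adjusted p = 4.5e-05, and adjusted p = 0.238 with an estimated correlation). Among 20 cytosolic synthetases 13 fell, Kars1 by 0.85, and 3 rose (adjusted p = 0.137). The transporters split into 5 higher, Slc6a9 by 1.76, and 6 lower of 15, with a median of -0.180, a mean of 0.0943 and a test direction down (adjusted p = 0.903). Of 30 cell cycle genes 29 fell (median -1.60, adjusted p = 1.1e-55), with Mki67 down by 1.77, Bub1b by 2.00, Kif11 by 1.63 and Plk1 by 1.86. Among 24 cholesterol genes 23 fell (median -1.15, adjusted p = 1.7e-22), Hmgcs1 by 1.68. All 20 nucleotide genes fell, Rrm1 by 1.80 (adjusted p = 1.9e-15, and adjusted p = 0.143 with an estimated correlation). Of 21 glycolysis genes 18 fell, Slc16a3 by 2.38, and 2 rose (adjusted p = 2.3e-11, and adjusted p = 0.144 with an estimated correlation). Of 18 naive and memory genes 14 rose and 4 fell, with Bach2 up by 1.85, S1pr1 by 2.52, Lef1 by 1.11 and Tcf7 by 0.54 (adjusted p = 4.8e-07, and adjusted p = 0.0894 with an estimated correlation). Effector genes had a median of -0.0921, a mean of 0.0253 and a test direction up (adjusted p = 0.963), and Gzmb fell by 0.41. The highest fold changes were those of Slfn5 (5.80), Ssc5d (4.31), Myof (3.93), the kinase gene Wnk4 (3.59), Arrdc4 (3.49) and Acoxl (3.43). Among the lowest were those of Fads2 (-3.18), H2bc12 (-2.86), Fbln1 (-2.66), H2ac11 (-2.66) and the ephrin receptor gene Ephb2 (-2.66). By edgeR 3391 genes were higher and 4110 lower, 7501 in total, with 1015 and 937 at 2-fold or more. Upper-quartile scaling gave 4254 higher and 3464 lower, which turned the majority from 45.2% to 55.1% higher, and RLE scaling gave 50.2%.

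Most genes that answered halofuginone in Rosa26 moved the same way in the knockouts. Between Rosa26 and Atf4 knockout cells 2504 genes rose and 2842 fell in both, where independent calls would give 800 and 941, with 79 opposite. Scd2, a desaturase, was among those 79, at -0.71 in Rosa26 and 0.75 in Atf4 knockout cells. For Cebpg knockout cells the numbers were 2700 and 3114, against 799 and 992, with 25 opposite. The correlation of the fold changes over all genes was 0.739 for the Atf4 and 0.812 for the Cebpg knockout. Genes that rose at least 2-fold in Rosa26 kept 77.0% of their median rise in Atf4 and 87.3% in Cebpg knockout cells. Genes that fell kept 106% and 112% of the fall. Editing efficiency was not analysed, so unedited cells may add to these shares. Choosing genes on the Rosa26 fold change inflates it. With genes chosen in 2 Rosa26 replicates and measured in the third, the shares of the rise were 91.7% and 103% and those of the fall 116% and 123%. Here the Rosa26 response was a difference of log2 CPM with a prior count of 2, while the knockout response came from the fit. That prior raises the shares, so their increase cannot be laid to the choice of genes alone. The rise in Atf4 knockout cells ran from 67.2% without Rosa26 halofuginone replicate 2 to 82.1% without Atf4 knockout halofuginone replicate 3.

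Without the drug, Atf4 knockout cells were compared with Rosa26 to ask what the gene does in culture alone. Genes of amino acid synthesis, tRNA charging, cholesterol synthesis, glycolysis and division were lower, and p53 targets and naive genes were higher. Asns fell from 43.0 to 21.3 CPM (-1.01 ± 0.088), Phgdh by 0.78, Psat1 by 0.59 and Mthfd2 by 0.51. Of 20 cytosolic synthetases 18 fell and 0 rose, and all 20 fell when adjusted over the list alone (median -0.378, adjusted p = 1.0e-16, and adjusted p = 0.0595 with an estimated correlation). The cysteinyl-tRNA synthetase gene Cars1 fell by 0.78, Yars1 by 0.64 and Tars1 by 0.57. Mitochondrial synthetases gave 4 higher, Wars2 by 0.65, and 2 lower of 17 (adjusted p = 0.211). Of 14 serine and one-carbon genes 10 fell and 0 rose (adjusted p = 2.5e-08, and adjusted p = 0.0868 with an estimated correlation). Of 15 genes of asparagine, proline and glutamate metabolism 10 fell and 0 rose (adjusted p = 1.2e-07, and adjusted p = 0.0944 with an estimated correlation). Among 21 integrated stress response targets 9 fell and 3 rose, among them Cdkn1a, which encodes p21, by 0.58 (adjusted p = 0.0468, and adjusted p = 0.625 with an estimated correlation). Trib3 was -0.31 (adjusted p = 0.0521). Among 15 transporters 7 fell, the large neutral amino acid transporter gene Slc7a5 by 0.44, and 1 rose (adjusted p = 0.0565). In glutathione and transsulfuration 6 of 15 fell, Gsr by 0.55, and 1 rose (adjusted p = 0.00271, and adjusted p = 0.395 with an estimated correlation).

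Of 24 cholesterol genes 22 fell in untreated Atf4 knockout cells (median -0.655, adjusted p = 9.5e-33), Insig1 by 1.16 and Hmgcs1 by 1.00. Among 21 glycolysis genes 17 fell and 0 rose (median -0.603, adjusted p = 2.0e-19), Slc16a3 by 1.15, Aldoa by 0.90 and Pgk1 by 0.81. Among 30 cell cycle genes 29 fell (median -0.552, adjusted p = 6.2e-35), with Birc5, which encodes survivin, down by 0.74, Cenpa by 0.69, Bub1b by 0.68 and Mki67 by 0.48. Among 20 nucleotide genes 19 fell, Rrm2 by 0.62 and Umps, a pyrimidine synthesis enzyme, by 0.58 (adjusted p = 2.8e-13, and adjusted p = 0.0944 with an estimated correlation). Among 17 p53 targets 11 rose and 0 fell (median 0.471, adjusted p = 1.4e-09), with Zmat3 up by 0.89. Among 18 naive and memory genes 11 rose and 2 fell (median 0.346, adjusted p = 8.3e-08), with the IL-7 receptor gene Il7r up by 0.88; Tcf7 was 0.02 (adjusted p = 0.871). Of 20 effector genes 7 fell, the IL-2 receptor gene Il2ra by 0.43, and 2 rose (adjusted p = 0.00858, and adjusted p = 0.395 with an estimated correlation). Checkpoint genes rose in 6 of 15 cases, Tnfrsf4, which encodes OX40, by 0.86 (adjusted p = 0.0383, and adjusted p = 0.254 with an estimated correlation). The CD4 T marker Foxp3 rose from 4.82 to 10.8 CPM (1.16), while that list had 2 higher and 2 lower genes, a median of -0.00375, a mean of 0.075 and a test direction down (adjusted p = 0.946). Chac1 fell by 0.85, Gzmb fell by 0.23 and Ddit3 rose by 0.76. These 3 calls ended when single libraries were left out, with adjusted p up to 0.138 for Chac1, 0.105 for Gzmb and 0.108 for Ddit3. For Gzmb this held for each of the 6 libraries, for Chac1 for each but Atf4 knockout replicate 1, and for Ddit3 for Rosa26 replicates 1 and 3 and Atf4 knockout replicate 1.

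The highest gene was Cacna1i, which encodes a T-type calcium channel and lies 2 annotated genes from Atf4. It had 136 to 146 counts in each untreated Atf4 knockout library (8.71 ± 0.292 CPM) against 0 to 7 in those of Rosa26, a ratio of means of 39.7. Next came Arrdc4 (1.73), Gnal (1.69), the immunoglobulin gene Igha (1.66), the laminin gene Lama5 (1.65) and Kit, a receptor kinase (1.63). The lowest were Scd1 (-2.02), the TNF family gene Tnfsf14 (-1.26), H2ac8 (-1.20), Insig1, Slc16a3 and Fads2 (-1.11). H2ac8 lost its call without Rosa26 replicate 3 (adjusted p = 0.0552) or Atf4 knockout replicate 3 (adjusted p = 0.0795). Unconfirmed transcripts had a median of 0.864, with 47 higher and 1 lower of 829. By edgeR 1720 genes were higher and 2107 lower, 3827 in total and 44.9% higher, of which 320 and 32 moved by at least 2-fold. Upper-quartile scaling gave 2330 higher and 1713 lower, 57.6% higher. A fit of only the 6 libraries compared called 5997 genes, and a fit without the 3 halofuginone libraries low in unconfirmed transcripts called 6164.

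Untreated Cebpg knockout cells had lower levels of some genes of amino acid synthesis, cholesterol synthesis and division. Asns fell from 43.0 to 25.8 CPM (-0.74 ± 0.0865), Pck2, the mitochondrial PEP carboxykinase, from 32.6 to 17.2 CPM (-0.92 ± 0.0992), Psat1 by 0.37 and Mthfd2 by 0.32. Trib3 was 0.00 (adjusted p = 0.988), Ddit3 was 0.20 (adjusted p = 0.636), Chac1 was -0.81 (adjusted p = 0.0928), Gzmb was -0.19 (adjusted p = 0.158) and Mki67 was -0.17 (adjusted p = 0.143). Of 21 integrated stress response targets 1 fell, Eif4ebp1 by 0.39, and 0 rose (adjusted p = 0.145). Among 24 cholesterol genes 12 fell and 0 rose, and 18 fell adjusted over the list alone (median -0.345, adjusted p = 5.2e-19, and adjusted p = 0.0594 with an estimated correlation); Insig1 fell by 0.71, Hmgcs1 by 0.52 and Idi1 by 0.55. Of 30 cell cycle genes 14 fell, and 20 adjusted over the list alone (median -0.290, adjusted p = 8.2e-20, and adjusted p = 0.166 with an estimated correlation), with cyclin B2, Ccnb2, down by 0.59, Cenpa by 0.43 and Birc5 by 0.40. Of 21 glycolysis genes 11 fell, Pgk1 by 0.42 and Aldoa by 0.43 (adjusted p = 1.7e-09, and adjusted p = 0.306 with an estimated correlation). Among 20 cytosolic synthetases 3 fell, Lars1 by 0.23, and 12 adjusted over the list alone (adjusted p = 3.4e-06, and adjusted p = 0.355 with an estimated correlation). Of 20 nucleotide genes 4 fell, and 16 adjusted over the list alone, Rrm2 by 0.30 (adjusted p = 3.8e-09, and adjusted p = 0.306 with an estimated correlation). Among 14 serine and one-carbon genes 3 fell (adjusted p = 0.000137, and adjusted p = 0.341 with an estimated correlation), and of 15 asparagine, proline and glutamate genes 3 fell (adjusted p = 1.9e-05, and adjusted p = 0.306 with an estimated correlation). None of 42 genes of oxidative phosphorylation passed, Atp5f1a being -0.30 (adjusted p = 0.0735), while the list was lower (median -0.203, adjusted p = 1.4e-06, and adjusted p = 0.676 with an estimated correlation).

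Naive genes rose in 5 of 18 cases in untreated Cebpg knockout cells, and in 9 adjusted over the list alone, with Slamf6 up by 0.62, and 2 fell (adjusted p = 0.00694, and adjusted p = 0.355 with an estimated correlation). Of 17 p53 targets 3 rose, Zmat3 by 0.42 (adjusted p = 0.00798, and adjusted p = 0.306 with an estimated correlation). The highest genes were Igha (1.21), Lama5 (1.17), the E-cadherin gene Cdh1 (1.00), Patj (0.87), Kit (0.86) and Gbp11 (0.81). The lowest were Scd1 (-1.20), the pseudogene Eif4a-ps4 (-1.002), Pck2, Asns, Insig1 and Zfp429 (-0.63); Gbp11 and Eif4a-ps4 may share reads with near copies. Without any 1 of the 6 libraries the calls of Phgdh (-0.37), Scd1, Gbp11 and Zfp429 ended, with adjusted p up to 0.141, 0.0769, 0.160 and 0.185. Without Cebpg knockout replicate 2, and for each gene without at least 2 other libraries too, those of Eif4a-ps4 (adjusted p = 0.139), Eif4ebp1 (adjusted p = 0.105), Lars1 (adjusted p = 0.103), Rrm2 (adjusted p = 0.0679) and Slc16a3 (adjusted p = 0.0642) ended. Unconfirmed transcripts had a median of 0.792, with 5 higher and 0 lower of 829. By edgeR 398 genes were higher and 337 lower, 735 in total and 54.1% higher, of which 43 and 5 moved by at least 2-fold. RLE scaling gave 402 higher and 1134 lower, 26.2% higher. DESeq2 called 1991 (25.2% higher), a fit of the compared libraries 4044, a filter of 5 CPM 1308, the fit without the 3 libraries 3932 and the fit with the covariate 1208. Leaving out Rosa26 replicates 1, 2 and 3 gave 258, 227 and 325 calls, and leaving out Cebpg knockout replicates 1, 2 and 3 gave 314, 203 and 264.

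With halofuginone, Atf4 knockout cells were compared with treated Rosa26 cells to ask which treated levels depend on the gene. Amino acid and tRNA charging genes stood far lower. Asns stood at 21.5 against 86.8 CPM (-2.01 ± 0.0871), Trib3 at 102 against 319 CPM (-1.64 ± 0.108) and Chac1 at 1.86 against 8.18 CPM (-2.13 ± 0.278). Psat1 fell by 1.52, Mthfd2 by 1.28 and Phgdh by 1.04, and Cebpg itself by 0.41 (adjusted p = 2.8e-05), while Ddit3 was -0.32 (adjusted p = 0.218). Among 21 integrated stress response targets 16 fell and 0 rose (median -0.994, adjusted p = 3.2e-16), Gpt2 by 2.03 and Lonp1, a mitochondrial protease, by 0.99. Of 20 cytosolic synthetases 18 fell (median -0.879, adjusted p = 6.6e-43), Cars1 by 1.22, Lars1 by 1.20 and Yars1 by 1.08. Of 14 serine and one-carbon genes 12 fell and 1 rose (adjusted p = 2.2e-22), with the folate gene Mthfd1l down by 1.02. Of 15 genes of asparagine, proline and glutamate metabolism 9 fell (adjusted p = 3.9e-16), with the branched-chain transaminase Bcat1 down by 1.28. Of 15 transporters 9 fell, Slc7a5 by 1.22 (adjusted p = 3.5e-12), and of 15 glutathione genes 10 fell, Txnrd1 by 0.93 (adjusted p = 1.4e-09). Of 17 mitochondrial synthetases 2 rose and 4 fell, Vars2 by 0.34 (adjusted p = 0.764).

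Division and cholesterol synthesis genes were lower in treated Atf4 knockout than in treated Rosa26 cells. Among 30 cell cycle genes 29 fell (median -0.750, adjusted p = 5.9e-43), Tpx2 by 1.02, Birc5 by 1.00, Bub1b by 0.94 and Mki67 by 0.58. Among 20 nucleotide genes 17 fell, Tk1 by 1.23 (adjusted p = 5.7e-16), of 24 cholesterol genes 19 fell (adjusted p = 1.9e-14), and of 21 glycolysis genes 17 fell, Pgk1 by 1.01, and 2 rose (adjusted p = 4.6e-13). Of 79 ribosomal protein genes 12 fell, and 4 adjusted over the list alone, Rpl14 by 0.53 (adjusted p = 0.00597, and adjusted p = 0.833 with an estimated correlation). Of 18 naive and memory genes 11 rose and 2 fell (median 0.440, adjusted p = 4.6e-07), with S1pr1 up by 1.11 and Tcf7 by 0.66. Of 15 checkpoint genes 7 rose, Btla by 0.44 (adjusted p = 0.000338), and of 17 p53 targets 10 rose, Trp53inp1 by 0.77, and 1 fell (adjusted p = 2.4e-06). Of 20 effector genes 6 fell, the cytokine gene Tnf by 0.71 and Gzmb by 0.36, and 3 rose (adjusted p = 0.0541). Zbtb7b fell by 1.55 among the CD4 T markers, of which 2 fell and 1 rose (adjusted p = 0.117).

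Cacna1i had 213 to 335 counts in the treated Atf4 knockout libraries (15.6 ± 4.57 CPM) and 0 in the treated libraries of both other genotypes, at least 90.6-fold above Rosa26 and 81.2-fold above Cebpg knockout with a floor of 3 counts per library. The next highest were Sdc4 (1.81), Abca1 (1.61), Kit (1.501), Cd7 (1.39) and the polymerase gene Poln (1.38). The lowest were Slc6a9 (-2.27), Cox6a2 (-2.22), Pck2 (-2.16), Chac1, Gpt2 and Asns. By edgeR 1731 genes were higher and 2397 lower, 4128 in total and 41.9% higher, with 103 and 200 at 2-fold or more. Upper-quartile scaling gave 2372 higher and 2171 lower, 52.2% higher, and a fit of only the compared libraries called 2500.

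In treated Cebpg knockout cells the same groups were lower than in treated Rosa26 cells. Asns stood at 29.9 against 86.8 CPM (-1.54 ± 0.0849), Trib3 at 77.8 against 319 CPM (-2.04 ± 0.110), Atf5 at 24.8 against 100 CPM (-2.01 ± 0.134) and Pck2 at 12.0 against 55.7 CPM (-2.21 ± 0.102). Chac1 fell by 1.71, Psat1 by 1.18, Mthfd2 by 1.06 and Phgdh by 0.75, and Ddit3 was -0.43 (adjusted p = 0.126). Of 21 integrated stress response targets 14 fell and 0 rose, and 17 fell adjusted over the list alone (median -0.666, adjusted p = 2.1e-24). Among 20 cytosolic synthetases 18 fell (median -0.578, adjusted p = 9.3e-35), Lars1 by 0.95, Eprs1, which encodes the enzyme halofuginone binds, by 0.88 and Yars1 by 0.70. Among 14 serine and one-carbon genes 10 fell (adjusted p = 3.0e-19), of 15 asparagine, proline and glutamate genes 9 fell, Got1 by 0.81 and Gpt2 by 1.59 (adjusted p = 1.5e-16), and of 15 transporters 9 fell, Slc7a5 by 1.06 (adjusted p = 7.1e-12). Of 15 glutathione genes 10 fell, Txnrd1 by 0.65 (adjusted p = 3.8e-09, and adjusted p = 0.0529 with an estimated correlation). Mitochondrial synthetases had a median of -0.0206, a mean of 0.0158 and a test direction up (adjusted p = 0.980).

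Of 30 cell cycle genes 28 fell in treated Cebpg knockout cells (median -0.563, adjusted p = 1.5e-34), Birc5 by 0.71, the cyclin gene Ccne1 by 0.66, Tpx2 by 0.62 and Mki67 by 0.34. Of 24 cholesterol genes 17 fell (adjusted p = 4.2e-14). Of 20 nucleotide genes 16 fell, Rrm2 by 0.73 (adjusted p = 4.7e-16, and adjusted p = 0.0529 with an estimated correlation), and of 21 glycolysis genes 17 fell, Pgk1 by 0.84, and 2 rose (adjusted p = 2.0e-13, and adjusted p = 0.0529 with an estimated correlation). Among 18 naive and memory genes 8 rose, Il7r by 0.52 and Tcf7 by 0.37, and 2 fell (adjusted p = 0.000126, and adjusted p = 0.0914 with an estimated correlation). Among 17 p53 targets 3 rose, Trp53inp1 by 0.40, and 2 fell (adjusted p = 0.225). Gzmb fell by 0.28, a call that ended without Cebpg knockout halofuginone replicate 1 (adjusted p = 0.0633). The highest genes were the microRNA gene Mir6236 (1.98), Kit (1.37), Acoxl (1.12), Pgap1 (1.11), Sbsn (1.06) and Abca1 (1.01). Mir6236 lost its call without any of 5 libraries (adjusted p up to 0.109), all but Cebpg knockout halofuginone replicate 1, and Sbsn without Rosa26 halofuginone replicate 2 (adjusted p = 0.0732) or Cebpg knockout halofuginone replicate 1 (adjusted p = 0.0723). The lowest were Cox6a2 (-3.10), Pck2, Trib3, Atf5, Angptl6 (-1.97) and Slc6a9 (-1.81). By edgeR 844 genes were higher and 1929 lower, 2773 in total and 30.4% higher, with 51 and 61 at 2-fold or more. Upper-quartile scaling gave 1543 higher and 1500 lower, 50.7% higher, and leaving out Cebpg knockout halofuginone replicate 1 gave 1775 calls.

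The treated knockouts were then set against each other. In the main fit some tRNA charging and division genes were higher and some p53 targets lower in Cebpg than in Atf4 knockout cells. Cars1 rose by 0.60 ± 0.0555, Nars1 by 0.45 ± 0.0648 and Yars1 by 0.38 ± 0.0532. Of 20 cytosolic synthetases 7 rose and 0 fell, and 12 rose adjusted over the list alone (median 0.222, adjusted p = 8.8e-19, and adjusted p = 0.0995 with an estimated correlation). Among 30 cell cycle genes 7 rose, and 20 adjusted over the list alone, Plk1 and Tpx2 by 0.40 each (adjusted p = 3.4e-19, and adjusted p = 0.0995 with an estimated correlation). Of 17 p53 targets 6 fell and 0 rose, and 11 fell adjusted over the list alone (median -0.263, adjusted p = 7.4e-16), with Trp53inp1 down by 0.37. Of 14 serine and one-carbon genes 2 rose, and 9 adjusted over the list alone, Mthfd1l by 0.36 (adjusted p = 2.4e-09, and adjusted p = 0.0995 with an estimated correlation). Naive and memory genes had 1 of 18 lower, and 8 adjusted over the list alone (adjusted p = 1.8e-05, and adjusted p = 0.113 with an estimated correlation). Integrated stress response targets had 1 higher and 1 lower of 21, with a median of -0.0925, a mean of 0.108 and a test direction up (adjusted p = 0.694). Trib3 was -0.39 (adjusted p = 0.102), Chac1 was 0.42 (adjusted p = 0.629) and Ddit3 was -0.10 (adjusted p = 0.901). Cebpg fell by 0.37 (adjusted p = 0.00442), Asns rose by 0.47, Psat1 by 0.34, Nupr1, a stress-induced gene, by 2.17 and the proline synthesis gene Pycr1 by 0.96, while the p53 targets Bbc3 and Phlda3 fell by 0.65 and 0.76. Without Cebpg knockout halofuginone replicate 1 the calls of Cebpg (adjusted p = 0.0504), Asns (adjusted p = 0.0878), Nupr1 (adjusted p = 0.0689), Pycr1 (adjusted p = 0.188), Bbc3 and Phlda3 (adjusted p = 0.0878 for both) ended, and without Atf4 knockout halofuginone replicate 1 those of Asns (adjusted p = 0.0518), Psat1 (adjusted p = 0.112) and Pycr1 (adjusted p = 0.155) did. Psat1 also lost its call without Cebpg knockout halofuginone replicate 3 (adjusted p = 0.0615), and Pycr1 without that library (adjusted p = 0.0556) or Atf4 knockout halofuginone replicate 2 (adjusted p = 0.065).

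Among genes of at least 5 CPM the highest in this comparison were Pycr1, the mitotic gene Troap (0.73), the cytokine gene Lif (0.72), Skp2 (0.63), the helicase gene Recql4 (0.62) and Dna2 (0.61). Cacna1i was the lowest, followed by Phlda3, Bbc3, Psrc1 (-0.65), Zfp874a (-0.63) and Rap2a (-0.63). Without Cebpg knockout halofuginone replicate 1, and for all but Troap without other libraries too, the calls of Troap (adjusted p = 0.0504), Lif (adjusted p = 0.0878), Skp2 (adjusted p = 0.190), Dna2 (adjusted p = 0.0689), Zfp874a (adjusted p = 0.109) and Rap2a (adjusted p = 0.0769) ended. By edgeR 79 genes were higher and 68 lower, 147 in total and 53.7% higher, with 2 and 1 at 2-fold or more. The total was 223 with RLE and 291 with upper-quartile scaling, 353 with a filter of 5 CPM, 492 with DESeq2 (42.1% higher), 1 in a fit of only the 6 compared libraries, 724 without the 3 libraries low in unconfirmed transcripts and 1160 with their share as a covariate. It was 90 with the replicate block. It was 22 without Cebpg knockout halofuginone replicate 1, 93 without its replicate 2, 53 without Atf4 knockout halofuginone replicate 1 and 404 without its replicate 3.

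The interaction with Atf4 knockout asked whether the response to halofuginone differed from that in Rosa26. Genes of the stress response, tRNA charging and amino acid transport rose less or fell more. The difference was -1.002 ± 0.123 for Asns, -1.33 ± 0.157 for Trib3, -0.93 ± 0.094 for Psat1, -0.77 ± 0.0797 for Mthfd2 and -0.54 ± 0.0864 for Cebpg. Ddit3 had -1.09 (adjusted p = 0.0367) and Chac1 -1.29 (adjusted p = 0.0603). Among 21 integrated stress response targets 9 were lower and 0 higher, and 14 lower adjusted over the list alone (median -0.613, adjusted p = 4.8e-13, and adjusted p = 0.121 with an estimated correlation), with Lonp1 at -0.68. Among 20 cytosolic synthetases 12 were lower, Lars1 by 0.86, Eprs1 by 0.63 and Nars1 by 0.61 (adjusted p = 1.8e-14, and adjusted p = 0.121 with an estimated correlation). Of 15 transporters 8 were lower, Slc7a5 by 0.78, the arginine transporter gene Slc7a1 by 0.48 and Slc6a9 by 1.36 (adjusted p = 6.4e-08, and adjusted p = 0.115 with an estimated correlation). Among 14 serine and one-carbon genes 5 were lower (adjusted p = 2.5e-09, and adjusted p = 0.121 with an estimated correlation). Of 30 cell cycle genes 10 were lower, Cdc6 by 0.53 and E2f1 by 0.48, and 1, Cenpa, was higher by 0.48 (adjusted p = 9.2e-06, and adjusted p = 0.487 with an estimated correlation). Tcf7 was higher by 0.63 (adjusted p = 0.00230), while its list of 18 naive and memory genes had no other call, a median of -0.109, a mean of -0.00618 and a test direction up (adjusted p = 0.941). Of 24 cholesterol genes 2 were higher and 2 lower (median 0.0972, adjusted p = 0.0462, and adjusted p = 0.876 with an estimated correlation). Glycolysis had a median of -0.0237, a mean of -0.0116 and a test direction up (adjusted p = 0.814). Foxp3 was lower by 0.96 and Cd8a by 0.49.

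The highest interaction values with Atf4 knockout were those of Scd1 (2.23), Nr4a1, an immediate early gene (1.83), Acoxl (1.79), Abca1 (1.58), Acsl3, a fatty acyl-CoA ligase (1.47), and Scd2 (1.46 ± 0.10). Scd2 went from 400 to 244 CPM in Rosa26, from 231 to 388 CPM in Atf4 knockout and from 308 to 330 CPM in Cebpg knockout cells. The lowest were those of Syt6 (-2.95), Gbp11 (-1.90), Atf5 (-1.82), Lama5 (-1.72), Angptl6 (-1.69) and Ncs1 (-1.54). The call of Ddit3 ended without any of 8 libraries, with the highest adjusted p, 0.111, without Atf4 knockout untreated replicate 1. That of Abca1 ended without any of 5, with the highest, 0.123, without Rosa26 untreated replicate 2. By edgeR 354 genes were higher and 589 lower, 943 in total and 37.5% higher, with 22 and 82 at 2-fold or more. RLE scaling gave 705 higher and 489 lower, 59.1% higher. The total was 607 in a fit of only the compared libraries, 1499 with DESeq2 (59.3% higher), 2192 without the 3 libraries low in unconfirmed transcripts and 2629 with their share as a covariate. Leaving out Rosa26 halofuginone replicate 2 gave 1455 calls (56.9% higher) and leaving out Atf4 knockout halofuginone replicate 3 gave 1477 (52.7% higher).

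The interaction with Cebpg knockout was also lower in the stress response, transporter and synthetase lists. The difference was -2.04 ± 0.157 for Trib3, -2.13 ± 0.207 for Atf5, -0.80 ± 0.121 for Asns, -0.81 for Psat1, -0.74 for Mthfd2 and -0.86 for Cebpg. Of 21 integrated stress response targets 7 were lower and 0 higher, and 12 lower adjusted over the list alone (median -0.628, adjusted p = 1.1e-23), with Lonp1 at -0.81. Of 15 transporters 7 were lower, Slc7a5 by 1.01, Slc1a4 by 1.49 and Slc6a9 by 1.87 (median -0.499, adjusted p = 3.0e-20). Of 20 cytosolic synthetases 10 were lower, Lars1 by 0.71, Eprs1 by 0.75 and Iars by 0.66 (median -0.383, adjusted p = 2.1e-24). Of 14 serine and one-carbon genes 6 were lower, Mthfd1l by 0.58 (median -0.406, adjusted p = 6.6e-13). In asparagine, proline and glutamate metabolism 5 of 15 were lower, Gpt2 by 1.31 (adjusted p = 1.5e-08, and adjusted p = 0.115 with an estimated correlation). Among 30 cell cycle genes 7 were lower, Cdc6 by 0.65, Ccne1 by 0.57 and E2f1 by 0.50 (adjusted p = 4.0e-12, and adjusted p = 0.138 with an estimated correlation). Tnf was lower by 0.66. The highest were Acoxl (1.42), Scd2 (0.81), Mylip (0.78), Ust (0.77), Prrg4 (0.70) and Klf10 (0.69), and Tcf7 was higher by 0.47. The lowest were Cox6a2 (-3.71), Atf5, Angptl6 (-2.08), Trib3, Slc6a9 and Zbtb7b (-1.71). Without Cebpg knockout untreated replicate 1, and for all but Cox6a2 without other libraries too, the calls of Acoxl (adjusted p = 0.124), Mylip (adjusted p = 0.0681), Ust (adjusted p = 0.124), Prrg4 (adjusted p = 0.0599), Tcf7 (adjusted p = 0.0969) and Cox6a2 (adjusted p = 0.0589) ended. By edgeR 55 genes were higher and 308 lower, 363 in total and 15.2% higher, with 2 and 32 at 2-fold or more. RLE scaling gave 154 higher and 224 lower, 40.7% higher, and upper-quartile scaling 150 higher and 303 lower, 33.1% higher. The total was 629 with DESeq2 (44.2% higher), 1053 without the 3 libraries and 1628 with the covariate, and 219, 216, 210 and 220 without Rosa26 untreated replicates 1 and 3 and Cebpg knockout untreated replicates 2 and 3. Leaving out Rosa26 halofuginone replicate 2 gave 434 calls (47.2% higher), leaving out Cebpg knockout halofuginone replicate 2 gave 244 (38.5% higher), and a fit of only the compared libraries gave 476 (46.4% higher).

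Setting the responses of the knockouts against each other left 2 genes past the threshold. Scd2 rose less in Cebpg than in Atf4 knockout cells (-0.65 ± 0.10, adjusted p = 0.0211), and the predicted gene Gm17767, outside the naming rule and taken after its value was seen, was 0.87 ± 0.101 (adjusted p = 0.000733). Trib3 was -0.71 (adjusted p = 0.262), Asns 0.20 (adjusted p = 0.842), Psat1 0.12 (adjusted p = 0.890) and Ddit3 0.46 (adjusted p = 0.846). Among 24 cholesterol genes 0 passed, and 7 were lower adjusted over the list alone, with Hmgcs1 at -0.43 (median -0.248, adjusted p = 2.7e-08, and adjusted p = 0.330 with an estimated correlation). Glycolysis was lower as a list (median -0.221, adjusted p = 1.7e-06, and adjusted p = 0.593 with an estimated correlation), as were ER chaperones (adjusted p = 0.00231, and adjusted p = 0.745 with an estimated correlation) and transporters (adjusted p = 0.0217, and adjusted p = 0.593 with an estimated correlation). Integrated stress response targets had a median of -0.0784, a mean of 0.0278 and a test direction down (adjusted p = 0.252). The call of Scd2 ended without any Atf4 knockout untreated library, Cebpg knockout untreated replicates 2 and 3 or Cebpg knockout halofuginone replicate 1, with adjusted p from 0.0957 to 0.141. By edgeR 990 genes had an unadjusted p under 0.05. DESeq2 called 40, upper-quartile scaling 11 (9 higher and 2 lower, 81.8% higher), a filter of 5 CPM 9, the fit without the 3 libraries 61 and the fit with the covariate 160. Leaving out Atf4 knockout halofuginone replicate 2 gave 4 calls, and leaving out any of the libraries that ended the call of Scd2 gave 1.

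Nearly all genes called in both knockouts moved in the same direction. Without halofuginone 366 genes were higher and 324 lower in both, where independent calls would give 46.6 and 48.3, and 1 was opposite. With it the numbers were 737 and 1715 against 99.4 and 315, with 0 opposite. For the interactions they were 50 and 241 against 1.32 and 12.3, with 0 opposite. The knockouts share the Rosa26 controls, which alone makes their fold changes correlate. Over all genes the correlation was 0.789 without and 0.733 with the drug and 0.636 for the interactions. Simulations sharing only the controls gave 0.497, 0.493 and 0.496. The covariance was 0.206, 0.158 and 0.174 against a simulated 0.0538, 0.0491 and 0.103. The 0.0491 and 0.103 may be too low, because the simulations missed the larger spread of treated libraries. Part of the overlap of calls may come from the shared controls. As the simulations held no change, their 0 genes called in both say nothing about a shared change.

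**Figure D3:**
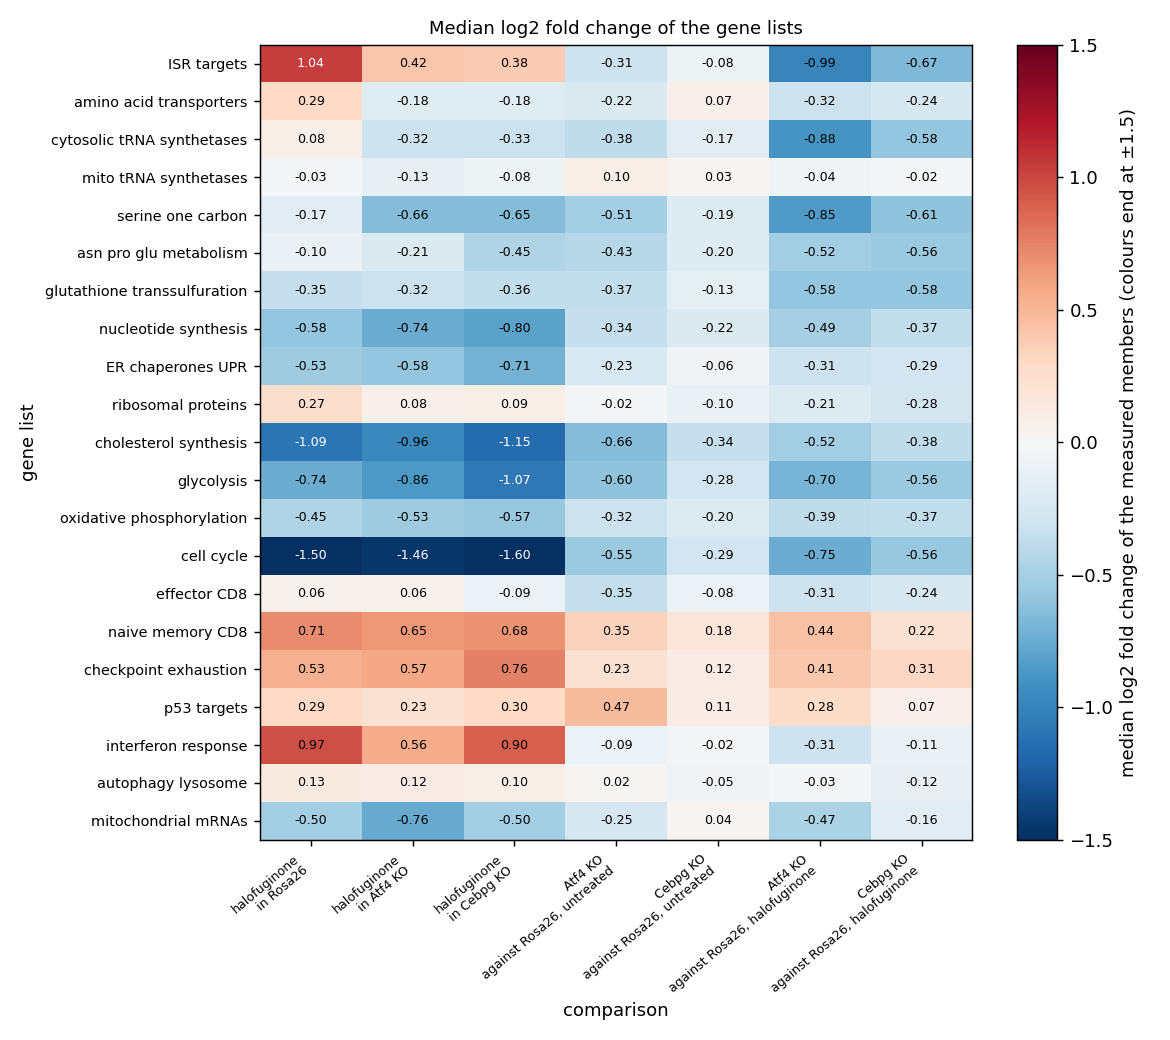
Median log2 fold change of the measured members of 21 gene lists (vertical axis) in 7 comparisons (horizontal axis), printed in each cell and coloured up to 1.5 in either direction. Integrated stress response targets had medians of 1.04, 0.42 and 0.383 with halofuginone in Rosa26, Atf4 knockout and Cebpg knockout cells, and cell cycle genes -1.5, -1.46 and -1.60.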

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

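The response to halofuginone differed between genotypes, which is what marked the values in this part; the tests of the 3 low libraries, of Cacna1i and of the covariate were chosen only after the results were seen. The count was 943 genes for Atf4 knockout against Rosa26, 363 for Cebpg knockout against Rosa26 and 2 for Cebpg against Atf4 knockout. For Atf4 knockout the differences were -0.54 for Cebpg, -1.002 for Asns, -1.33 for Trib3, -1.09 for Ddit3, -0.93 for Psat1 and -0.77 for Mthfd2. They were -1.82 for Atf5, -1.69 for Angptl6, -1.72 for Lama5, -1.54 for Ncs1, -2.95 for Syt6 and -1.90 for Gbp11. On the higher side they were 0.63 for Tcf7, 2.23 for Scd1, 1.46 for Scd2, 1.83 for Nr4a1, 1.79 for Acoxl, 1.58 for Abca1 and 1.47 for Acsl3. For Cebpg knockout they were -0.86 for Cebpg, -0.80 for Asns, -2.04 for Trib3, -0.81 for Psat1, -0.74 for Mthfd2, -2.13 for Atf5, -2.08 for Angptl6, -1.87 for Slc6a9, -1.71 for Zbtb7b and -3.71 for Cox6a2. On the higher side they were 0.47 for Tcf7, 1.42 for Acoxl, 0.81 for Scd2, 0.78 for Mylip, 0.77 for Ust, 0.70 for Prrg4 and 0.69 for Klf10. Between the knockouts Scd2 differed by -0.65.

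Chance was tested by relabelling the libraries. For the interaction with Atf4 knockout 3 of 30 regroupings, the real one included, called at least as many genes as the real 943, and the highest other called 4592. For Cebpg knockout 4 of 30 reached the real 363, with 1169 as the highest other, and between the knockouts 4 of 30 reached the real 2, with 50. Chance is therefore not excluded by this test for any of the 3. As seen after the counts, each other regrouping that reached 943 or 363 left the genotype labels of 1 treatment as they were and changed 4 of 6 in the other, and the one with 50 changed all 6 untreated labels and 2 with halofuginone. Such labels bring the difference between the genotypes into the interaction by design, so these high counts need not come from chance or from a structure of the samples. Without regroupings of this kind the highest other values were 334, 319 and 2.

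For the comparisons of 3 against 3 libraries there are 10 splits, so no share under 0.05 can be reached. The real split was the only one to reach its count in 7 of 8. The highest other split called 0 genes against the real 7008, 7294 and 7501 for halofuginone in Rosa26, Atf4 knockout and Cebpg knockout. It called 0 against 3827 and 735 for the untreated Atf4 and Cebpg knockouts, and 0 against 2773 for the treated Cebpg knockout. It called 1297 against 4128 for the treated Atf4 knockout and 421 against 147 for Cebpg against Atf4 knockout with halofuginone, where 2 of 10 splits reached the real count. Both of these other splits put the libraries low in unconfirmed transcripts together, as 4 of 10 splits do. The 4 such splits for the treated Cebpg knockout called 0 genes, so a link between these libraries and the high counts stays open.

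The halofuginone library of each genotype with the fewest unconfirmed transcripts may hold fewer unspliced or nuclear RNAs. The 140 sense intronic genes had medians of -1.64, -1.59 and -0.817 against the other libraries of the group, with 97.9%, 96.4% and 90.7% lower. Genomic DNA in the other libraries stays open, since it may set part of a gene's level. The excess per kilobase was 3.28, 3.31 and 3.49 times larger in genes of high than low level, where uniform DNA gives about 1. The bootstrap intervals (95%, 1000 draws) were 2.91 to 3.74, 2.97 to 3.70 and 3.09 to 4.02. The preset rule asked for a ratio of 3, which 2 intervals reach below. The limit of 1.5 on the interval came after the ratios were seen. A different strength of response is argued against, with slopes of -0.0840, -0.132 and -0.0397. Whether the cause lay in RNA isolation or the cells stays open.

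Higher unconfirmed transcripts in both untreated knockouts might reflect a larger share of unspliced RNA that moves other genes. With their share as a covariate the median called coding gene kept 82.6% of its fold change in Atf4 knockout (quartiles 67.9% and 98.8%) and 80.2% in Cebpg knockout (quartiles 70.3% and 95.9%), and 3064 of 3509 and 627 of 675 calls stayed. The medians of the unconfirmed transcripts went from 0.86 to -0.14 and from 0.79 to -0.10. This argues against the share as the whole cause, and it leaves open whether it moved part of the values.

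Cacna1i counts in Atf4 knockout cells may come from a change at the edited locus, since the gene lies 2 annotated genes from Atf4, an observation made after the counts were seen. Of 11 measured neighbours of Atf4, 2 passed the threshold without and 5 with halofuginone, and 0 of those that passed moved by 2-fold. Mgat3, outside the naming rule and taken after its value was seen, was 1.17 with halofuginone (adjusted p = 0.0648) at under 1 CPM. Reads shared with related calcium channels could not be judged, since 0 of the 2 closest relatives were analysed here. Whether the transcript starts at Cacna1i or runs on from the edited gene stays open, because no reads were used here.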

How the results depend on the processing

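The labels do not say which libraries share an animal or a culture, and the replicate numbers did not pair them: over 45 same-number pairs the median correlation was -0.00525 (from -0.687 to 0.527, 9 above 0.1), over 90 other pairs it was 0.00601, and 6 of 18 libraries correlated best with their own number. The genotype labels were not checked by the mRNA of the targeted genes. Gene lengths and order came from an older build than the counts, and genes that share reads are uncertain. The settings built on unconfirmed transcripts were chosen after the data were seen. Direction was compared only for values of named genes called in the main fit or in the setting, and none of these turned. The settings run for single genes were DESeq2 (608 values), limma-voom (613), the replicate block, RLE scaling, the covariate and the fit without the 3 libraries (635 each), and 1 library left out (4774). The cause of the moves below was not tested unless a cause is given.

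For untreated Atf4 knockout (3827 calls) a fit of only the compared libraries gave 5997 and a fit without the 3 low halofuginone libraries 6164. For untreated Cebpg knockout (735) these fits gave 4044 and 3932, RLE scaling 1536, a filter of 5 CPM 1308, DESeq2 1991 and the covariate 1208. For treated Atf4 knockout (4128) the compared libraries alone gave 2500. For Cebpg against Atf4 knockout with halofuginone (147) RLE gave 223, upper-quartile scaling 291, the filter of 5 CPM 353, the compared libraries alone 1, DESeq2 492, leaving out the 3 libraries 724 and the covariate 1160. For the interaction with Atf4 knockout (943) the compared libraries alone gave 607, DESeq2 1499, leaving out the 3 libraries 2192 and the covariate 2629. For the interaction with Cebpg knockout (363) DESeq2 gave 629, leaving out the 3 libraries 1053 and the covariate 1628. For the interaction between the knockouts (2) upper-quartile scaling gave 11, the filter 9, DESeq2 40, leaving out the 3 libraries 61 and the covariate 160.

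With the replicate block the calls were 6789, 7089 and 7264 for halofuginone in Rosa26, Atf4 and Cebpg knockout, 3547 and 507 for the untreated and 3886 and 2491 for the treated Atf4 and Cebpg knockouts. They were 90 for the treated knockouts against each other, 783, 273 and 2 for the interactions, and the genes lower in both untreated knockouts went from 324 to 200. The replicate block weakened 23 of the 635 values of named genes and strengthened 0.

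Leaving out 1 library at a time gave 6148 to 7292 calls for halofuginone in Rosa26, 6545 to 7601 in Atf4 knockout and 6726 to 7091 in Cebpg knockout. It gave 2756 to 3150 for untreated Atf4 and 203 to 325 for untreated Cebpg knockout, where each of the 6 libraries lowered the count. It gave 3302 to 5265 for treated Atf4 and 1775 to 2872 for treated Cebpg knockout, and 22 to 404 for the treated knockouts against each other. For the interactions it gave 650 to 1477 with Atf4, 210 to 434 with Cebpg and 1 to 4 between the knockouts. Of 4774 values of named genes with a library left out, 286 became weaker and 36 stronger.

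The share of the rise kept in Atf4 knockout (77.0%, SD 5.02 over the 3 treated knockout libraries) was 91.7% with genes chosen and measured in different Rosa26 replicates, 67.9% without the 3 low libraries, and 67.2% to 82.1% with 1 library left out. The share of the fall (106%, SD 7.37) was 116% with that cross-choice, 87.1% at a fold change of at least 2 (log2), and 99.9% to 108% with 1 left out. In Cebpg knockout the share of the rise (87.3%, SD 2.72) was 103% with the cross-choice, 84.3% at a log2 fold change of at least 2, 90.8% with RLE, 76.0% without the 3 libraries, and 79.0% to 89.9% with 1 left out. The share of the fall (112%, SD 1.87) was 123% with the cross-choice, 117% with genes of any size, 85.2% at a log2 fold change of at least 2, 108% with RLE, 105% without the 3 libraries, 104% with the covariate, and 104% to 114% with 1 left out.

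Genes higher in both untreated knockouts (366) numbered 1573 without the 3 libraries, 652 with the covariate and 93 at an adjusted p under 0.01. Genes lower in both (324) numbered 1051 with RLE, 1838 without the 3 libraries and 68 at that threshold. With halofuginone, genes higher in both (737) numbered 1255 with the covariate and 358 at that threshold, and genes lower in both (1715) numbered 1074. For the interactions, genes higher in both (50) numbered 137 with RLE, 201 without the 3 libraries, 303 with the covariate and 12 at that threshold, and genes lower in both (241) numbered 591, 950 and 98 with the last 3 of these.

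Of 141 calls of gene lists, 36 stayed with an estimated correlation. Among named genes DESeq2 weakened 1 and strengthened 33 of 608 values, limma-voom weakened 8 and strengthened 1 of 613, RLE weakened 3 and strengthened 17, the covariate weakened 7 and strengthened 60, and leaving out the 3 libraries weakened 4 and strengthened 51. A filter on a total above 0 added no gene.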

Other observations

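Some genes of lipid metabolism are given here that were picked after their values were seen, and apart from cholesterol synthesis no list of lipid genes was tested. Scd1 went from 8.53 to 1.05 CPM with halofuginone in Rosa26, from 2.10 to 1.21 CPM in Atf4 knockout and from 3.70 to 1.02 CPM in Cebpg knockout cells, so its interaction value of 2.23 came with an untreated level that was already lower. Acsl3 went from 14.1 to 3.67 CPM in Rosa26 and from 6.61 to 4.80 CPM in Atf4 knockout cells in the same way. Scd2 differed, since it rose to 388 CPM in treated Atf4 knockout cells from 231 CPM. Abca1 and Acoxl rose in all genotypes, to 14.2 and 11.8 CPM in Atf4 knockout against 4.68 and 4.76 CPM in Rosa26 cells. Fasn, a gene outside the naming rule that encodes fatty acid synthase, fell with halofuginone by 1.12 in Rosa26, 1.04 in Atf4 and 1.21 in Cebpg knockout cells.

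Kit, Igha and Cdh1 were higher in both knockouts and rose with the drug, also seen only after the values were. Kit stood at 2.76 CPM in untreated and 12.5 CPM in treated Rosa26 cells, and at 35.2 and 32.3 CPM in treated Atf4 and Cebpg knockout cells. Igha stood at 2.54 and 13.4 CPM in Rosa26 and at 27.5 and 20.9 CPM in the treated knockouts. Cdh1 stood at 4.25 and 15.1 CPM in Rosa26 and at 28.4 and 24.6 CPM in the treated knockouts. Reads of the ribosomal RNA gene Rn18s-rs5 took 2.25% to 7.28% of the counts of a library, and Lars2, a mitochondrial synthetase gene, ran from 1921 to 9478 CPM.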
